A study of Rattus norvegicus with 9 samples.

How the data were processed

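Gene expression was measured in peripheral blood mononuclear cells (PBMC) of 9 male Wistar rats, 4 fed chow and 5 fed a cafeteria diet, with 1 array per animal on a rat whole-genome oligonucleotide array read in 2 colours. Each array carried Cy5-labelled RNA of 1 animal and a Cy3-labelled reference pooled over all samples, always in that dye orientation. Per the labels, 1 further control was left out by the authors for too little RNA.

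Each scanner file deposited by the authors gives the mean spot and median local background intensity of both dyes, read by the scanner software without normalization. The same files hold, per the file headers, a log10 ratio of Cy5 over Cy3 after the software's background subtraction and its linear and lowess dye normalization. A table of values per spot deposited by the authors is on a log2 scale and filled for 21466 of 45220 spots. Its values followed the Cy5 intensity of each array (rank correlation across spots 0.993 to 0.999), so it was read as a Cy5 level, and how the reference entered it is unknown. Because medians of that table ran from 9.40 to 9.69 between arrays, its values were not centred.

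The intensities were the starting point. Background was corrected by normexp with an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with control spots given no weight. Spots that the scanner software marked as non-uniform or as population outliers were left out, and repeated spots of a probe were averaged. Probes were kept when Cy5 was well above background on at least 4 arrays, the size of the smaller group, which left 25805 of 41012 probes. These steps used limma 3.58.1 with statmod 1.5.0 and the package data.table (version 1.17.8) in R 4.3.3, and Python 3.11.15 with matplotlib 3.10.9.

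Gene names in the files were updated through a RefSeq gene table by transcript accession, then by symbol, then by synonym, which matched 19482 probes (47.5%). The remaining probes kept the name in the file. A name matched only by spelling was dropped where the file placed the probe on another chromosome than the gene table did (46 probes matched by symbol lost their name). That naming step was added after the values were seen, when a probe named Ttr in the file proved to lie on the mitochondrial chromosome. Positions are those in the files, on the rn4 build per the file headers, and neither exon nor untranslated region is given for a probe.

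The depth of each array is given by its signal above background, since arrays give no counts. Cy5 was well above background for 58.8% to 66.7% of 43379 spots other than controls. The number of arrays limits the precision.

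Cafeteria and control arrays were compared per probe with limma (moderated, 7 residual and 2.94 prior degrees of freedom), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Values in the text are log2 fold changes of cafeteria over control with the standard error (SE), or group means with the standard deviation (SD). A gene was represented by its probe of highest mean signal, which gave 22088 genes or unnamed transcripts. Gene lists were tested with camera from limma at a preset correlation of 0.01, again with a correlation estimated per list, and by a two-sided exact permutation test of the list mean over the 126 splits of the 9 arrays into 4 and 5, whose smallest possible p is 0.00794. Separation of the groups over all probes was tested by a one-sided exact permutation test of the mean distance between arrays of different groups minus that within groups.

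The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where a later choice is named as such. The 22 pathway lists were fatty acid uptake and activation; mitochondrial and peroxisomal fatty acid oxidation; fatty acid and triacylglycerol synthesis; sterol synthesis and uptake; sterol efflux and LXR targets; glycolysis and glucose uptake; oxidative phosphorylation; cytosolic ribosomal proteins; insulin, leptin and adiponectin signalling; interferon response; inflammatory cytokines and NF-kB targets; antigen presentation by MHC class II; antigen presentation by MHC class I and proteasome; cell cycle; unfolded protein and integrated stress response; heat shock response; oxidative stress and NRF2 targets; hypoxia response; immediate early and handling response; circadian clock; glucocorticoid-responsive genes; and apoptosis. The 10 cell type lists held markers of T cells, cytotoxic T and NK cells, B cells, plasma cells, monocytes, neutrophils, platelets and megakaryocytes, erythroid cells, dendritic cells, and basophils, mast cells and eosinophils.

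Genes with a symbol were named by a rule with several parts. It takes up to 10 genes per direction past the adjusted threshold, filled up to 10 with the genes of smallest unadjusted p whose group values did not overlap. It adds up to 4 members of each list called by camera, in the direction of the list, and 20 genes named whatever their values, of which 2 are not reported here. For lists that were not called the rule allows at most 2 genes, and none was taken. All 20 genes needed to fill the 10 per direction came from below the adjusted threshold.

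The arrays lay on 7 slides scanned on 1 day. Slide 3 held control 1 and cafeteria 1, slide 5 held control 13 and cafeteria 10, and every other slide held 1 array. Slide was therefore tried as a block, and the differences within slides 3 and 5 are given. A fixed block on slide leaves the comparison to slides 3 and 5 alone, so its value is the mean of these differences. It is no further evidence beside them, and its tests have little left to estimate the spread from. Replicate numbers 1, 4, 7 and 13 occur in both groups. After group means were removed, arrays of the same number correlated across probes by -0.05, 0.11, 0.099 and -0.15, and number 4 alone passed the threshold of 0.1 set for pairing, so the arrays were treated as unpaired and a block on the replicate number was tried as an alternative.

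Each alternative replaced 1 choice and kept the rest: no background correction, the scanner software's log ratio, median centring, Aquantile normalization between arrays (which leaves log ratios as they are, so that nothing moved), the Cy5 channel alone, the authors' table, no filter and a stricter filter, outlier spots kept, blocks on slide or replicate number, array weights, a trended and robust prior, other thresholds, the mean of all probes of a gene, and leaving out each array. Slide as a random block, the probe nearest the 3' end and the authors' table centred on each array's median were added after the data were seen. The authors' table brings other background and dye handling, a level in place of a ratio and 20164 probes at once, and the replicate block drops cafeteria 10, which has no partner.

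The procedure was tested on simulated data with the same design and 25805 probes, each drawn independently of the others. limma recovered 100% of probes shifted by 2 on the log2 scale, 90.0% of those shifted by -1 and 67.5% of those shifted by 0.5 (40 probes each), and called 5 of 25605 unchanged probes. Camera called the list shifted by 0.2 and 0 of the other 31. Because probes were drawn independently, this says nothing of calls that correlated genes give, and the correlation estimated per list in the data reached 0.71. The adjustment is also more lenient where many probes are shifted, as here, than in the data, where 2 passed. The recovered shares are thus not those to be had in the data. There Cpt1a at 0.53 and Slk at -0.92 had limma adjusted p of 0.46 and 0.229.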

Results

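Gene expression was profiled in the mononuclear cells of peripheral blood (PBMC), the lymphocytes and monocytes that a Ficoll density gradient separates from red cells and granulocytes. The cells came from 9 male Wistar rats aged 6 months and bled while fed. In the control group 4 animals ate standard chow, and in the cafeteria group 5 animals had palatable, fat-rich foods beside the chow for 4 months, from the age of 2 months, a diet used to make rats obese. Cy5 signal was well above background for 58.8% of spots on the array with the fewest (cafeteria 1) and 66.7% on the array with the most (control 7). The comparison asks which genes of circulating blood cells differ with diet-induced obesity, with genes of fat and energy handling among those of interest.

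The gene furthest apart between the groups was Slc27a2, a fatty acid transporter and very long-chain acyl-CoA synthetase (chromosome 3, 114114177 to 114114236). Its log2 ratio to the reference was 0.68 ± 0.49 (SD, n = 5) in cafeteria animals and -3.52 ± 2.16 (SD, n = 4) in controls, a log2 fold change of 4.2 (SE 0.82, 18.4-fold). Cpt1a, the carnitine palmitoyltransferase that commits fatty acids to mitochondrial oxidation (chromosome 1, 205912066 to 205912125), was at 0.12 ± 0.12 (SD, n = 5) against -0.41 ± 0.15 (SD, n = 4), a difference of 0.53 (SE 0.09). Genes of fatty acid oxidation and markers of erythroid cells were higher as lists (mean differences 0.090 and 0.20), and markers of T cells were lower (-0.13). With an estimated correlation between genes none of these lists passed (lowest adjusted p 0.514). Neither Slc27a2 nor Cpt1a passed the adjusted threshold over all genes (limma adjusted p = 0.78 and 0.46). What passed it was a single transcript, CF111195, which was lower in cafeteria animals.

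Across all 25805 probes, 2 had an adjusted p under 0.05 by limma, both of them lower and both from CF111195. Whatever their p, 14018 probes were higher and 11787 lower. At an unadjusted p under 0.05 there were 1136 probes, 398 higher and 738 lower, against 1290 given by chance. At an unadjusted p under 0.01 there were 42 higher and 202 lower, so 82.8% were lower, a share that came to 77.4% without background correction, 68.8% with the scanner software's log ratio, 70.2% with Cy5 alone, 55.3% with median centring, and 27.3% with the authors' values or 84.0% after these were centred. The share with median centring rests on only 21 lower and 17 higher probes. The authors' values before centring shift the median of all probes by 0.13. Values of the groups did not overlap for 328 probes (1.27%), where chance gives 1.59%. The mean distance between arrays of different groups exceeded that within groups by 0.0028 on the log2 scale, a difference not beyond that of other splits (one-sided exact permutation p = 0.302, with 38 splits giving at least as much).

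CF111195 is an expressed sequence tag with no gene symbol, so it lies outside the rule for named genes and was named after its values were seen. Its called probes fell by 1.04 (SE 0.10) and by 0.91 (SE 0.10) on the log2 scale, both with a limma adjusted p of 0.0372. The first stood at 1.03 ± 0.20 (SD, n = 4) in controls and -0.01 ± 0.14 (SD, n = 5) in cafeteria animals, and on both probes every cafeteria value lay below every control value. The files give no position for these probes but place the other probes of CF111195 on the mitochondrial chromosome at bases 1289 to 1348 and 1557 to 1613, the part that in rat mitochondrial DNA holds the genes of the ribosomal RNAs. Over 12 probes of CF111195 and of the forward strand up to base 1613, log2 fold changes ran from -1.04 to -0.21. Their median was -0.58, and 11 had an unadjusted p under 0.05. Base 1613 is where the last placed CF111195 probe ends, the called probes are among the 12, and several of the 12 overlap in position. They are thus not independent, and values of the groups did not overlap for 5 of them. In contrast, 17 probes of the mitochondrial protein-coding genes COX1, COX2, COX3, ATP6, CYTB, ND2 and ND5 ran from -0.10 to 0.15 with a median of 0.034, and 0 had an unadjusted p under 0.05. Between scalings the median of the first set ran from -0.78 (median centring) to -0.35 (Cy5 alone), and that of the protein-coding genes from -0.077 (median centring) to 0.14 (the authors' values, shifted as a whole by 0.13). Both calls ended with every scaling that changes the log ratios (Aquantile normalization between arrays leaves them as they are), from -1.27 (SE 0.32) and -1.12 (SE 0.29) with median centring to -0.27 (SE 0.07) and -0.26 (SE 0.08) with Cy5 alone, and also with slide as a fixed block (-0.96, SE 0.13, and -0.91, SE 0.14), a replicate block, array weights, and a trended and robust prior; the limma adjusted p ran from 0.0286 to 1.00 for the first probe. Within slides 3 and 5 the first probe differed by -1.03 and -0.89, signs that were bound to agree because the groups did not overlap. Without any of control 1, 4 or 7 or of cafeteria 1, 7, 10 or 13 the adjusted threshold was missed. The first probe then lay between -1.07 and -0.97.

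**Figure D1:**
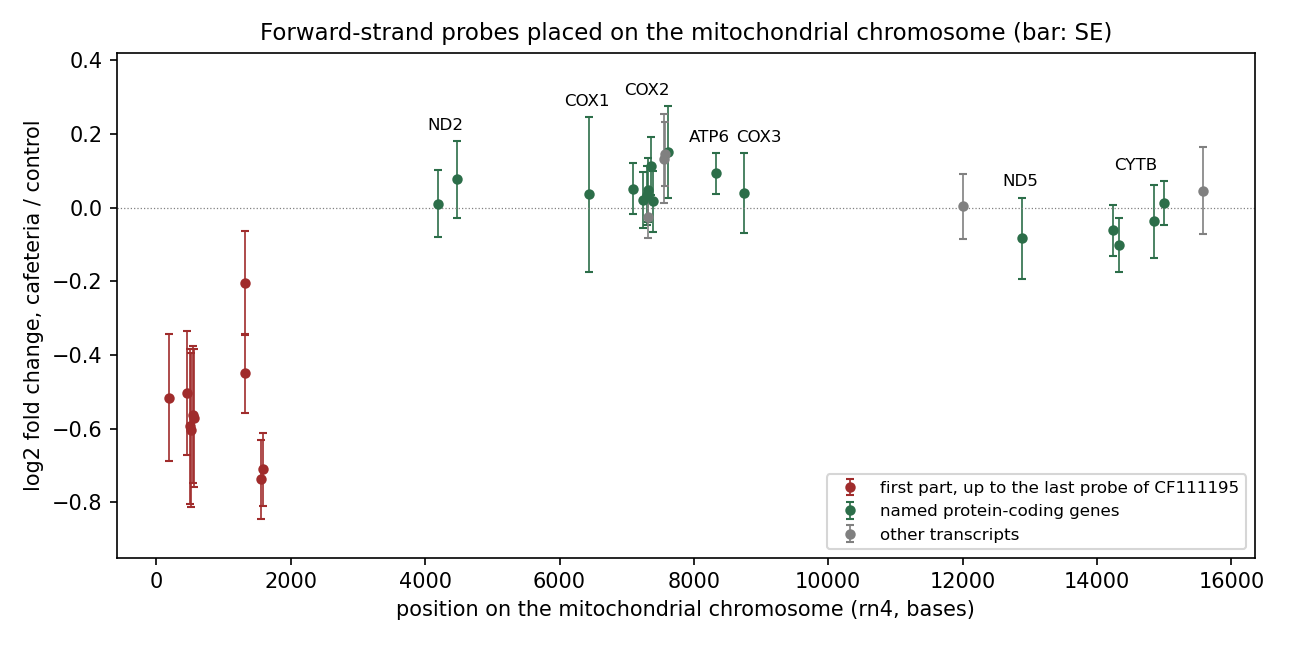
Log2 fold change (cafeteria over control, with SE) of forward-strand probes against their position in bases on the mitochondrial chromosome, for 4 control and 5 cafeteria arrays. Probes up to base 1613 lie below 0, and those of named protein-coding genes lie between -0.10 and 0.15, a range that moves down with median centring (median -0.077) and up with the authors' values (median 0.14).

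Among genes named for a small p and groups that did not overlap, 10 were higher in cafeteria animals, and none of them passed the adjusted threshold. Beside Slc27a2 and Cpt1a they were Ahsp (1.02, SE 0.21), the chaperone of alpha globin; Tgm2 (0.93, SE 0.23), a transglutaminase; Alas2 (0.61, SE 0.15), the first enzyme of haem synthesis in erythroid cells; Car2 (0.57, SE 0.09), a carbonic anhydrase abundant in red cells; and Rgl1 (0.32), Mgmt (0.32), Armc5 (0.31) and Ptgr2 (0.30). Slc27a2 had a second probe at 3.15 (SE 0.66), with controls 1, 4, 7 and 13 at -0.097, -1.83, -3.78 and -3.53. On the first probe controls were split, with -0.32 in control 1 and -4.85 to -4.14 in the others. The cafeteria arrays ran from 0.098 to 1.38 on the first probe. Without control 1 the log2 fold change was 5.27 (SE 0.28) and the limma adjusted p was 0.00058, against 0.168 to 1.00 over the alternatives that kept all arrays. As groups did not overlap for these 10 genes, their signs within slides 3 and 5 were bound to agree. Slc27a2 differed by 1.28 within slide 3, which holds control 1, by 4.95 within slide 5, and by 3.11 with slide as a block. Alas2 came to 0.34 and Ptgr2 to 0.45 with that block. Without cafeteria 7, Car2 came to 0.65 (SE 0.06) with a limma adjusted p of 0.0495.

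The 10 genes named as lower did not pass the adjusted threshold either. They were Ptpn11 (-1.16, SE 0.24), the phosphatase SHP2; Wac (-0.94, SE 0.19); Slk (-0.92, SE 0.13), a STE20-like kinase with adjusted p = 0.229 by limma; Cpne3 (-0.77, SE 0.16); Csnk1a1 (-0.72, SE 0.15), a casein kinase; Fyco1 (-0.65); Atrx (-0.62), a chromatin remodeller; Pip4k2a (-0.54); Cyfip2 (-0.42) and Dnajb6 (-0.39). Slk stood at -0.25 ± 0.22 (SD, n = 5) in cafeteria animals and 0.67 ± 0.22 (SD, n = 4) in controls. Second probes of Ptpn11 (-0.97), Cpne3 (-0.57) and Csnk1a1 (-0.51) were lower too, each with an unadjusted limma p under 0.01. A second probe of Dnajb6 had the opposite sign (0.058), and those of Wac (-0.13), Atrx (-0.22), Pip4k2a (-0.15) and Cyfip2 (-0.11) lay nearer 0. In these 5 of the 10 genes only the upstream probe had an unadjusted p under 0.01, a pattern found in 53 genes. As all 10 genes were chosen for groups that did not overlap, their signs within slides 3 and 5 were bound to agree. Within these slides Ptpn11 differed by -0.48 and -0.85 (-0.67 with slide as a block).

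**Figure D2:**
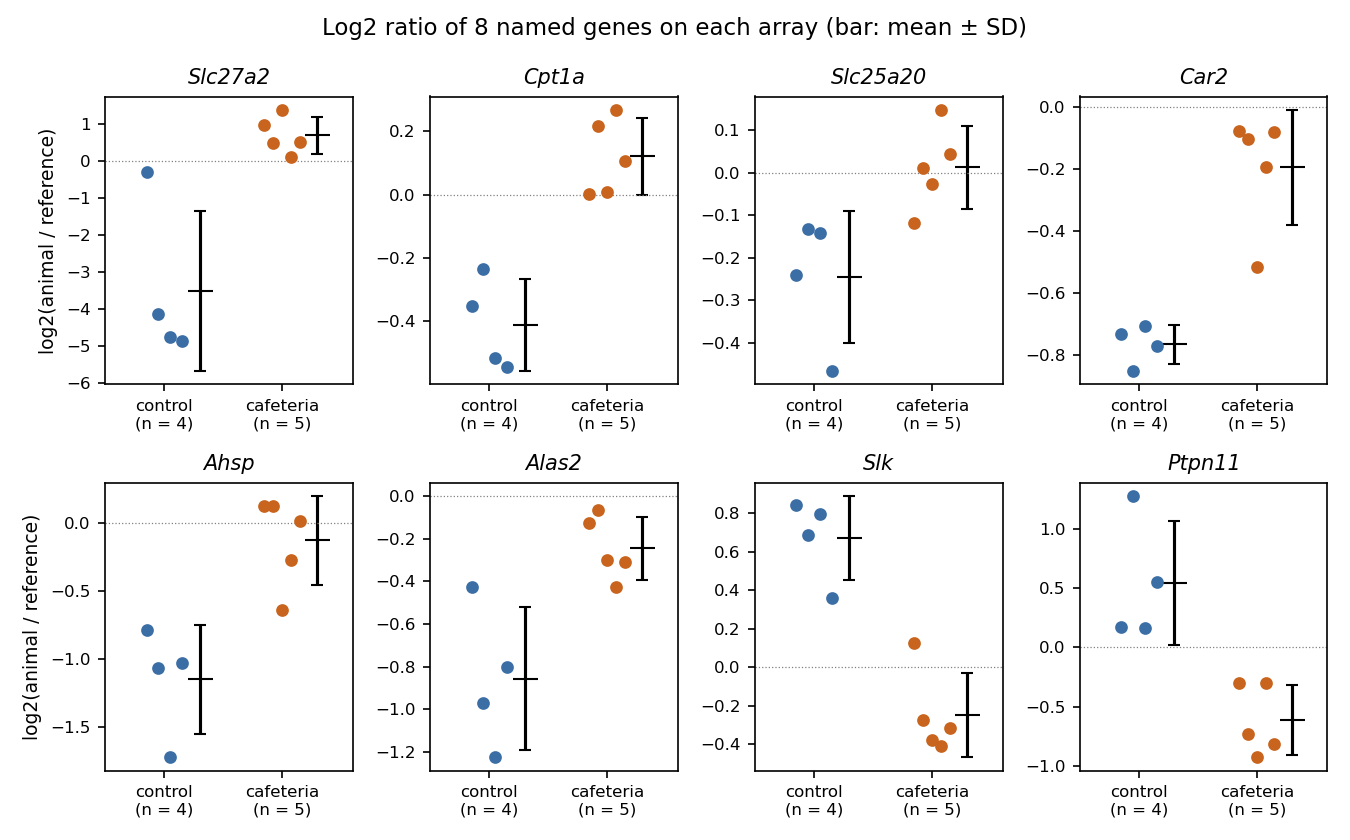
Log2 ratio of animal over reference of 8 named genes on each array (points; bars are mean and SD) for control (n = 4) and cafeteria (n = 5) animals. Slc27a2 lies between 0.098 and 1.38 on the cafeteria arrays and at -4.14 or below on every control array except control 1 (-0.32).

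In fatty acid oxidation, 22 of 27 measured genes were higher and 5 lower in cafeteria animals, with a mean difference of 0.090 and a camera adjusted p of 0.00216. With an estimated correlation the adjusted p was 0.514, and the exact permutation p of the list mean was 0.0238 (0.381 after adjustment). Beside Cpt1a, the examples are Acaa2 (0.32, SE 0.12; 0.086 with slide as a block) and Acads (0.25, SE 0.10), enzymes of the oxidation cycle, and Slc25a20 (0.26, SE 0.08), which carries acylcarnitines into mitochondria. Decr1, an auxiliary enzyme for unsaturated fatty acids named after its values were seen, was at -0.30 (SE 0.11). Cpt1a was the 1 gene that passed when adjusted over the list alone, and 0 passed over all genes tested. The list mean differed by 0.067 within slide 3 and 0.11 within slide 5, and with median centring it was 0.12 (camera adjusted p = 0.0504). It was 0.27 with the authors' values and 0.14 after these were centred. In the same samples the means of erythroid markers (0.20), B cell markers (0.23) and cytotoxic T and NK cell markers (0.17, or -0.095 with slide as a block) were higher, and those of T cell (-0.13) and platelet markers (-0.26) lower.

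In fatty acid uptake and activation, 10 of 14 genes were higher, and the list mean of 0.06 ± 0.06 (SD, n = 5) in cafeteria animals against -0.27 ± 0.13 (SD, n = 4) in controls gave an exact permutation p of 0.00794, the smallest that the splits can give. After adjustment over the 32 lists it was 0.254, the camera adjusted p was 0.114, and with an estimated correlation the adjusted p was 0.648. When adjusted over the list alone, 1 gene passed, Slc27a2, whose size sets the mean of 0.33, since the list median was 0.044. Cd36, which also takes up fatty acids, was at 0.13 (SE 0.20), at -0.034 with slide as a block and at 3.56e-06 without cafeteria 10. With median centring the list was called (0.38, camera adjusted p = 0.0227). Over the alternatives the mean ran from 0.24 (no filter) to 0.65 (the authors' values, or 0.52 after these were centred, with 10 of the genes).

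Erythroid markers were higher for 19 of 25 genes, by a mean of 0.20 (camera adjusted p = 1.33e-06). The adjusted p with an estimated correlation was 0.514 and the exact permutation p was 0.0556. There were 5 genes that passed when adjusted over the list alone and 0 over all genes tested: Car2, Ahsp, Alas2 and Hemgn (0.42, SE 0.13) among the higher, and Epb41 (-0.25, SE 0.08), a membrane skeleton protein not limited to red cells, among the lower. Hbb, the beta globin chain, was at 0.52 (SE 0.21), with means of -0.65 in cafeteria animals and -1.17 in controls. Rhag, another erythroid membrane protein, was at -0.71 (SE 0.53); Epb41, Hbb and Rhag were named after their values were seen. The list mean was 0.38 with the scanner software's log ratio, and 0.44 with the authors' values or 0.32 after these were centred. It differed by 0.29 within slide 3 and 0.23 within slide 5.

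B cell markers were higher for all 15 measured genes, by a mean of 0.23 (camera adjusted p = 1.59e-05), with an adjusted p of 0.722 with an estimated correlation. Examples are Fcmr (0.38, SE 0.16), the receptor for IgM; Blk (0.36, SE 0.17), a kinase of B cell receptor signalling; and Blnk (0.25, SE 0.12) and Cd37 (0.20, SE 0.09), all 4 of them below 0 within slide 3. The mean differed by -0.026 within slide 3 and 0.54 within slide 5, and it was 0.39 with the authors' values or 0.27 after these were centred. Markers of cytotoxic T and NK cells were higher for 18 of 25 genes, by a mean of 0.17 (camera adjusted p = 7.17e-04; adjusted p = 0.776 with an estimated correlation), but by -0.095 with slide as a block, and by -0.14 and -0.051 within slides 3 and 5. The mean was 0.099 without control 4 (camera adjusted p = 0.0946) and 0.090 without cafeteria 7 (0.00730), and the call ended with median centring (0.15, adjusted p = 0.130). The authors' values gave 0.30, or 0.18 after centring. Among the examples are Ncr1 (0.49, SE 0.17), an NK receptor, Nkg7 (0.38, SE 0.14) and Tbx21 (0.32, SE 0.11), the transcription factor T-bet. Tyrobp (0.40, SE 0.15, second probe 0.099), a signalling adaptor that is also on the monocyte list, is another. These 4 came to 0.17, 0.10, 0.15 and 0.056 with slide as a block. Adjusted over the list alone 0 genes passed among B cell or cytotoxic markers.

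T cell markers were lower for 22 of 26 genes, by a mean of -0.13 (camera adjusted p = 5.25e-05; adjusted p = 0.776 with an estimated correlation). Bcl11b (-0.51, SE 0.15; second probe -0.17) and Foxp3 (-0.24, SE 0.07), transcription factors of T cells, and the costimulatory receptors Icos (-0.29, SE 0.09; -0.52 with slide as a block) and Cd28 (-0.26, SE 0.09) are examples. The mean was -0.023 with the authors' values or -0.15 after these were centred, -0.078 without cafeteria 13 and -0.20 without control 4, and it differed by -0.012 within slide 3 and -0.36 within slide 5. Platelet markers were lower for 16 of 18 genes, by a mean of -0.26 (camera adjusted p = 0.00216; adjusted p = 0.776 with an estimated correlation), with F13a1 (-0.65, SE 0.39), Rgs18 (-0.47, SE 0.33), Gp9 (-0.44, SE 0.28) and Mylk (-0.35, SE 0.17; second probe -0.11) as examples, which came to -0.33, -0.24, -0.25 and -0.17 with slide as a block. Without control 4 F13a1 was at -0.30, Rgs18 at -0.22 and Gp9 at -0.12. Without control 4 that mean was -0.038 (camera adjusted p = 0.613), without cafeteria 1 it was -0.16 (0.118) and without cafeteria 7 it was -0.13 (0.182). Within slides 3 and 5 it differed by -0.32 and 0.19, and with slide as a block it was -0.064 (0.451). Adjusted over the list alone 0 genes passed in either list.

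Per animal, no mean of the 10 cell type lists passed an exact permutation test after adjustment over these lists (lowest adjusted p = 0.556), which 1 list alone cannot pass with 9 arrays (0.0794 at best), and the lowest unadjusted exact permutation p were 0.0556 for erythroid and 0.159 for B cell markers. Plasma cell markers were lower for 10 of 10 genes (mean -0.14), but the mean was 0.0087 without control 1 and -0.030 without cafeteria 1. It differed by -1.05 within slide 3 and 0.20 within slide 5 (-0.42 with slide as a block, camera adjusted p = 0.00395). Dendritic cell markers were lower for 5 of 9 genes (-0.063, or 0.042 with slide as a block, with -0.23 and 0.31 within slides 3 and 5). Neutrophil markers were lower for 13 of 19 genes (-0.067, or 0.0016 without cafeteria 7 and 0.063 with the authors' values). Markers of basophils, mast cells and eosinophils were higher for 8 of 11 genes (0.075, or 0.021 without cafeteria 10 and 0.18 with slide as a block, camera adjusted p = 0.00395). Monocyte markers were higher for 11 of 24 genes, with a mean of -0.018 (0.076 without cafeteria 1) and a median of -0.0078, whereas the camera statistic pointed up (adjusted p = 0.951).

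**Figure D3:**
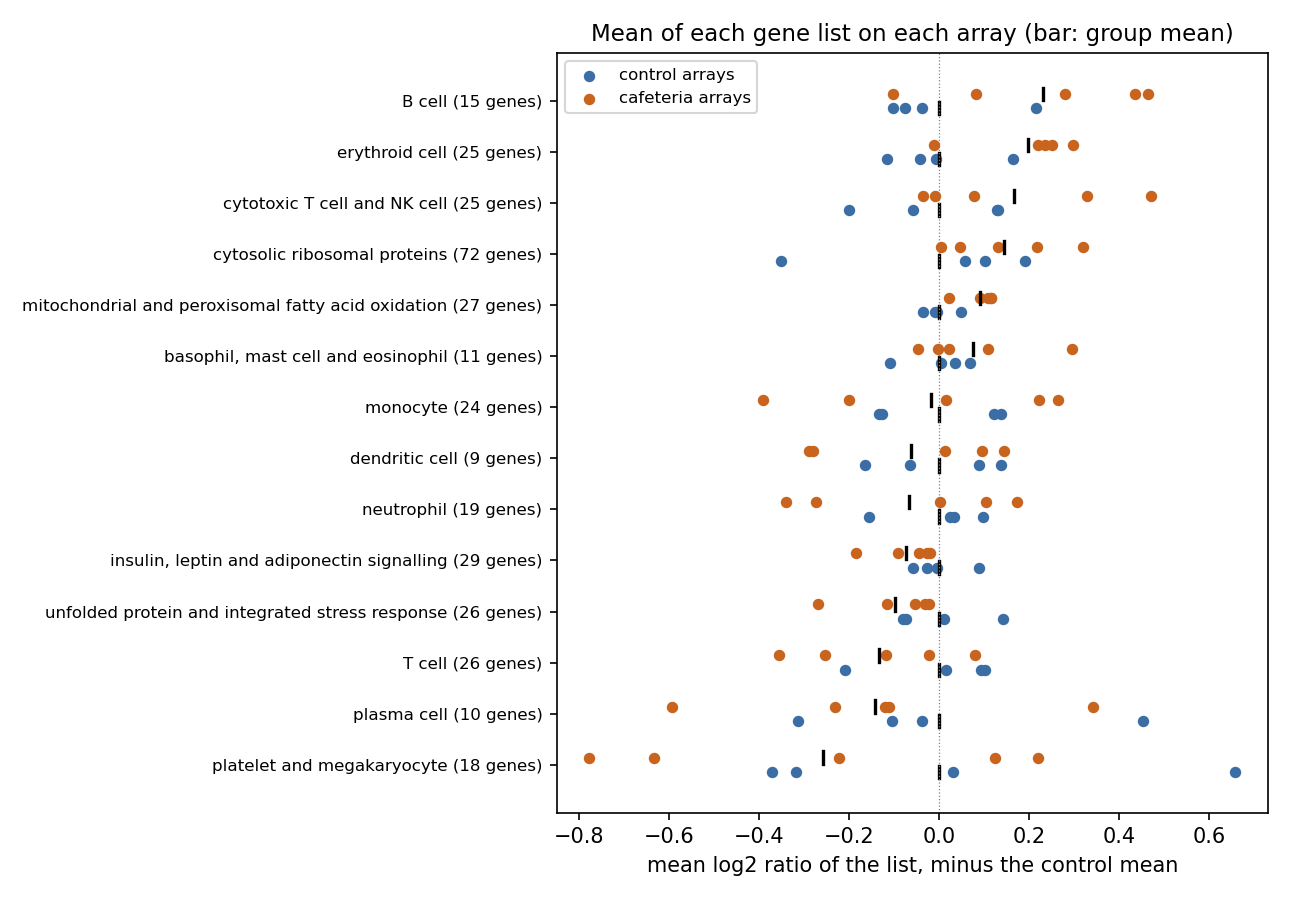
Mean log2 ratio of each list of genes on each array, less the control mean (points; black bars are group means), for the 10 cell type lists and for pathway lists called by camera at the preset correlation. Array means of controls (n = 4) and cafeteria animals (n = 5) overlap in every list drawn, and the ribosomal, insulin, unfolded protein, cytotoxic, plasma cell, monocyte, neutrophil and dendritic lists turn sign under an alternative setting or without 1 array.

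Cytosolic ribosomal proteins were higher for 65 of 72 genes, by a mean of 0.14 (camera adjusted p = 1.33e-06; adjusted p = 0.776 with an estimated correlation), but by -0.062 with median centring and by -0.015 with slide as a block. Rpl7 (0.40, SE 0.19), Rps3a (0.31, SE 0.14), Rpl11 (0.23, SE 0.12) and Rps12 (0.20, SE 0.10) are examples, which came to 0.18, 0.087, -0.017 and 0.092 with slide as a block. Without control 4 Rps3a was at 0.19, Rpl11 at 0.13 and Rps12 at 0.094, and without cafeteria 4 Rpl7 was at 0.26. The mean was 0.034 with no background correction, 0.036 with the scanner software's log ratio, 0.047 with Cy5 alone and 0.17 with the authors' values or 0.046 after these were centred (camera adjusted p = 0.431, 0.555, 0.176, 0.250 and 0.154), so the call ended there too. Without control 4 it was 0.027 (camera adjusted p = 0.478), and within slides 3 and 5 it differed by 0.12 and -0.15. Adjusted over the list alone 0 genes passed.

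Genes of the unfolded protein and integrated stress response were lower for 17 of 26 genes, by a mean of -0.098 (camera adjusted p = 0.0369; adjusted p = 0.776 with an estimated correlation). The authors' values put that mean at 0.025, against a median of all probes shifted by 0.13, and at -0.098 after centring; with slide as a block it was -0.18. Calr (-0.78, SE 0.18), the chaperone calreticulin, was the 1 gene that passed when adjusted over the list alone. Other examples are Atf6 (-0.34, SE 0.16), a sensor of unfolded protein, Trib3 (-0.27, SE 0.16) and Edem1 (-0.14, SE 0.09; other probes -0.032 and -0.097). Atf6 was at -0.23 without control 1, Trib3 at -0.41 without cafeteria 13 and Edem1 at -0.059 without control 7. The call ended with the scanner software's log ratio (camera adjusted p = 0.0846), median centring (0.0709), the authors' values (0.141, or 0.166 after centring), array weights (0.162) and the probe nearest the 3' end (0.0651). It also ended without control 1 (-0.051, 0.385), control 4 (-0.094, 0.127), cafeteria 1 (-0.055, 0.372) and cafeteria 4 (-0.094, 0.0550), and the mean differed by -0.41 within slide 3 and 0.042 within slide 5. Control 1 was highest and cafeteria 1 lowest in this list (0.12 and -0.29), as in plasma cell markers (0.43 and -0.61), whereas cafeteria 7 was at -0.043 and 0.32. Both lists hold Xbp1 and Edem1, so they are not independent. In insulin, leptin and adiponectin signalling 19 of 29 genes were lower, by a mean of -0.074 (camera adjusted p = 0.0411; adjusted p = 0.722 with an estimated correlation), or 0.050 with the authors' values and -0.072 after these were centred. Leprot (-0.48, SE 0.17), made from the leptin receptor locus, Jak2 (-0.25, SE 0.13), Foxo1 (-0.25, SE 0.11) and Pik3r1 (-0.12, SE 0.07) are examples, and 0 genes passed when adjusted over the list alone. Without control 4 Leprot was at -0.31 and Jak2 at -0.16, and without control 1 Pik3r1 was at -0.061. With slide as a block Pik3r1 was at -0.19, with -0.33 and -0.061 within slides 3 and 5. Control 4 was highest in this list (0.087) and in platelet markers (0.76), and cafeteria 1 and 7 were lowest in both (-0.19 and -0.094, against -0.54 and -0.68). Within slides 3 and 5 the mean differed by -0.16 and -0.015, and the call ended without control 4 (-0.044, camera adjusted p = 0.273), cafeteria 1 (-0.046, 0.355) or cafeteria 7 (-0.070, 0.0563). It ended as well with no background correction, the scanner software's log ratio, median centring, Cy5 alone (-0.044), the authors' values with or without centring, no filter, slide as a block and array weights (camera adjusted p from 0.0662 to 0.364).

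Taking all 32 lists, camera at the preset correlation called 9, of which 5 were higher and 4 lower. None was called with an estimated correlation (lowest adjusted p 0.514) or by the exact permutation test after adjustment (lowest 0.254, which is also the lowest that 1 list alone can reach), where 2 lists had an unadjusted p under 0.05. Camera adjusted p values of the lists that were not called lay between 0.114 and 0.951.

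Counts of higher genes are to be read against all 25805 probes tested, of which 14018 were higher and 11787 lower. Among pathways that were not called, genes of fatty acid and triacylglycerol synthesis were higher for 11 of 21 genes (mean -0.023). Those of sterol synthesis and uptake were higher for 15 of 26 (-0.013), and of sterol efflux and LXR targets for 9 of 14 (0.016). Glycolysis and glucose uptake had 12 of 25 genes higher (-0.012) and oxidative phosphorylation 39 of 55 (0.025). The interferon response had 17 of 41 genes higher (0.0076), inflammatory cytokines and NF-kB targets 17 of 29 (-0.032), antigen presentation by MHC class II 10 of 14 (0.050) and by MHC class I and the proteasome 21 of 27 (0.031). Cell cycle genes were higher for 15 of 35 (-0.010), heat shock genes for 12 of 17 (0.051), oxidative stress and NRF2 targets for 16 of 28 (-0.024) and hypoxia genes for 11 of 19 (-0.0038). Immediate early genes were higher for 15 of 30 (-0.026), circadian clock genes for 11 of 18 (0.047), glucocorticoid-responsive genes for 12 of 17 (0.11) and apoptosis genes for 19 of 33 (0.018). The direction of most of these means was not stable: of the 23 lists not called, cell types included, 17 turned sign under an alternative and 14 without 1 array. There were 5 that turned in neither case (fatty acid uptake, heat shock, circadian clock, glucocorticoid-responsive genes, and basophils, mast cells and eosinophils). Yet without 1 array the mean ran from 0.010 to 0.092 for heat shock, 0.031 to 0.077 for the circadian clock (0.018 with slide as a block) and 0.060 to 0.19 for glucocorticoid-responsive genes. These 3 lists also had opposite signs within slides 3 and 5: 0.085 and -0.040, -0.056 and 0.092, and -0.15 and 0.30. Slide as a block turned fatty acid and triacylglycerol synthesis (0.023), oxidative phosphorylation (-0.010), the interferon response (-0.090, camera adjusted p = 0.00395), MHC class I (-0.045) and apoptosis (-0.027). Of the 23 lists, 11 were called by camera under at least 1 alternative or without 1 array. The median and the mean differed in sign for fatty acid and triacylglycerol synthesis (median 0.012), sterol synthesis and uptake (0.015), the interferon response (-0.042), inflammatory cytokines (0.055), oxidative stress (0.020) and hypoxia (0.0023). Here camera took the sign of the median for the interferon, inflammatory and oxidative stress lists and that of the mean for the others. Adjusted over the list alone, 1 gene passed in the glucocorticoid list (Tgm2) and 1 in the MHC class I list (Calr), and 0 in the other lists of this group.

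Of 18 genes named whatever their values, 14 could be tested. Ccl2, a chemokine that draws monocytes, was at -0.84 ± 0.60 (SD, n = 5) in cafeteria animals and -0.06 ± 0.17 (SD, n = 4) in controls. Its difference was -0.79 (SE 0.27) and that of Il1b -0.60 (SE 0.28), neither past the adjusted threshold (limma adjusted p = 1.00 for both). Both were lowest in cafeteria 1 and 7 (Ccl2 -1.59 and -1.26, Il1b -1.02 and -0.83). The other cafeteria arrays had Il1b at 0.11 to 0.34, against 0.27 to 0.51 in controls. Monocyte markers (-0.41 and -0.22) and neutrophil markers (-0.35 and -0.42) were also lowest in cafeteria 1 and 7. Srebf1, which drives fatty acid synthesis, was at -0.18 (SE 0.16; second probe -0.091). It came to -0.039 without control 7 and to 0.048 with slide as a block, with 0.45 and -0.35 within slides 3 and 5. Its targets Fasn and Scd were at -0.055 (SE 0.07; second probe -0.035) and 0.077 (SE 0.14), or 0.034 and 0.29 with slide as a block. Abca1, which exports cholesterol, was at 0.15 (SE 0.13), or 0.031 without cafeteria 10 and up to 0.49 over the alternatives (scanner software's log ratio). With slide as a block it was 0.27, with -0.12 and 0.66 within slides 3 and 5. Ucp2, a mitochondrial carrier, was at 0.072 (SE 0.13; -0.059 without control 7 and 0.17 without control 4), Adipor1 at -0.20 (SE 0.16; -0.042 without control 4 and -0.32 without control 7) and Adipor2 at -0.035 (SE 0.09; second probe -0.092), with Adipor1 and Adipor2 being the adiponectin receptors. Insr (-0.028, SE 0.07) and Il6 (0.077, SE 0.06) were dim, with Cy5 above background on 3 and 2 arrays of each group. The signs of Cd36, Adipor2, Insr, Fasn, Scd, Srebf1 and Ucp2 turned under at least 1 alternative or without 1 array, and Il6 was at 0.038 without cafeteria 13 and 0.56 with the scanner software's log ratio. Lpl and Tnf were above background on 2 arrays at most and Pdk4 and Lepr on 0, so they were not tested.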

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

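The tests of the list counts over other splits, of the correlation with upstream recovery and of the chromosome segment around Slc27a2 were chosen beforehand, and all others here (gene counts and lower probes over other splits, normalization, probe position, mitochondrial protein-coding genes, saturation, the second Slc27a2 probe and a gene variant), with their bounds, were chosen only after the result was seen.

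In 9 of 196 groups of values 1 array lay far from the others of its group, which is 4.59% where chance gives 5%. For Slc27a2 control 1 was at -0.32 and the other controls at -4.85 to -4.14. Car2 was at -0.52 in cafeteria 7, with the others at -0.19 to -0.077, and the mean of the erythroid list was at -0.36 in the same animal, with the others at -0.13 to -0.053. Slk was at 0.13 in cafeteria 1, with the others at -0.41 to -0.27. Calr was at -0.19 in cafeteria 4, with the others at -0.70 to -0.58, and the mean of the fatty acid oxidation list was at -0.022 there, with the others at 0.046 to 0.071. Blk was at -0.044 in control 4, with the others at -0.54 to -0.47. Trib3 was at -0.15 in control 1 (others 0.22 to 0.27) and at 0.44 in cafeteria 13 (others -0.37 to -0.21).

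The test took 100 of the splits of the 9 arrays into 4 and 5, the real one included. Of these, 2 called at least the 2 probes that the real one called, and the highest of the others called 6. That share is under 0.05, but the test was chosen after the calls were seen, and both called probes come from the same transcript. It therefore cannot exclude chance for the number of probes called. The share holds for the main scaling alone. With every other scaling that changes the log ratios 0 probes were called, and the splits were not run there. For the gene lists chance cannot be excluded, since 40 of the 100 splits called at least the 9 lists of the real one and the highest of the others called 20.

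Of the probes with an unadjusted p under 0.01, 202 were lower and 42 higher in cafeteria animals. Chance cannot be excluded, because 21 of the 100 splits gave at least 202 probes in 1 direction. The highest of the others gave 1158, which points to a structure of the samples whose nature was not tested. This count takes no account of the share: 1 such split gave 381 probes at a share of 52.3%, and another 393 at 92.5%. Normalization stays open, since the share of lower probes, 82.8%, came to 55.3% with median centring. There, however, it rests on only 21 lower and 17 higher probes. The share was 27.3% with the authors' values, which are shifted as a whole, and 84.0% once these were centred. Recovery of the part of a transcript far from its 3' end is a candidate explanation, because where only 1 probe of a gene was lower it was the upstream one for 82.8% (53 genes against 11); yet only 36.6% of the lower probes have a partner, 6 of the 100 splits gave a share as high, and the mean upstream difference between the groups, -0.045, had an exact permutation p of 0.159. An effect of the diet was not tested apart from these and stays open.

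Probes of CF111195 and of the mitochondrial ribosomal RNA region were lower in cafeteria animals, with a median log2 fold change of -0.58. Fewer mitochondrial transcripts in general are argued against by the protein-coding genes (median 0.034), and saturation of Cy5 by 0 saturated Cy5 values in the region. Saturation of Cy3 in the region was not tested. Poorer recovery of upstream sequence cannot be told apart with 9 arrays: the region and the upstream measure, each less its group mean, correlated by r = -0.13 (permutation p = 0.753; rho = -0.12, permutation p = 0.787; 1 correlation tested), or 0.062 without the 2 farthest arrays. A change of ribosomal RNA with diet may remain, as may a difference in how RNA without a long poly(A) tail was copied, and neither was tested.

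Slc27a2 was higher on every cafeteria array than on every control array. A fault of 1 probe is argued against by the second probe (3.15, SE 0.66), and loss of a chromosome segment by the 41 probes within 1000000 bases (median 0.0037, from -0.22 to 0.20). A variant of the gene carried by some animals cannot be told apart from an effect of diet. A gap of at least 2 between arrays was found for 22 probes, 18 of them with 1 array apart. The other 4, Slc27a2 included, had 2 or more arrays on the smaller side. A share of 0.0476 of assignments would put all 3 low arrays of Slc27a2 among the controls, under the bound of 0.05 set for a variant. Because every cafeteria value lay above every control value, low arrays were bound to be controls, so this share decides nothing. The 3 arrays are low on the first probe, whereas on the second control 4 lay between the other controls (-1.83). Both the diet and such a variant stay open.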

How the results depend on the processing

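The centred version of the authors' table, slide as a random block and the probe nearest the 3' end were chosen only after the data were seen, and the other alternatives before. The number of probes called, 2 at the start, was 0 with no background correction, the scanner software's log ratio, median centring, Cy5 alone, the authors' values with or without centring, slide as a fixed block, a replicate block, array weights, and a trended and robust prior, where limma gave between 274 (median centring) and 2572 (authors' values) probes at an unadjusted p under 0.05. With the probe nearest the 3' end it was 0, but the called probes have no position and could not be chosen there, so this says nothing of their calls. It was 1 with the mean of all probes of a gene, and 244 and 1136 at an unadjusted p under 0.01 and 0.05; over the alternatives the lowest adjusted p ran from 0.0106 to 1.00. Leaving out each array gave 0 to 2. Lists called by camera, 9 at the start, were 0 with an estimated correlation and 0 by exact permutation, which 1 list alone cannot pass either, and 4 (without control 4) to 12 when an array was left out. The count of 0 cell type lists says nothing of stability, since with these splits 1 list alone cannot pass. The separation of the groups, 0.0028, was -0.025 with median centring and -0.0028 to 0.0070 when an array was left out.

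Of 64 named genes, 54 kept their sign in every alternative and without each array, as did 5 of the 9 called lists. The count of genes partly reflects how they were chosen. For the 10 per direction whose groups did not overlap, neither a left-out array nor a block on slide or replicate could turn the sign. Members of called lists were chosen in the direction of the list. With no background correction Insr came to 0.0052; with the scanner software's log ratio Adipor2 to 0.014; and with median centring Rpl11 to -0.0090, Rps12 to -0.058 and the ribosomal list to -0.062 (adjusted p = 0.00345, called the other way). The authors' values, shifted as a whole by 0.13, gave Adipor2 0.14 (0.020 after centring), Fasn 0.088, the insulin list 0.050 and the unfolded protein list 0.025. Slide as a fixed block by construction leaves out every array that shares no slide with the other group. It gave Cd36 -0.034, Fasn 0.034, Insr 0.0048, Rpl11 -0.017, Srebf1 0.048, Ucp2 -0.035, the ribosomal list -0.015 and the cytotoxic list -0.095. A replicate block, which by construction leaves out cafeteria 10, gave Scd -4.77e-05; array weights gave Adipor2 0.025 and Insr 0.0032; and the probe nearest the 3' end gave Dnajb6 0.058. Leaving out each array moved Adipor2 from -0.084 to 0.017, Insr from -0.057 to 0.024, Scd from -0.00087 to 0.20 and Ucp2 from -0.059 to 0.17. With the authors' values centred, Fasn (-0.035), the insulin list (-0.072) and the unfolded protein list (-0.098) kept the sign of the main values, so for their turns with the authors' values the shift is the cause; Dnajb6 turned because another probe was used, and for the others the cause was not tested. The permutation tests of separation and of cell type means were not run with a slide block, since only 2 slides hold both groups. Aquantile normalization moved nothing and says nothing of stability. Signal over background limits Insr and Il6, which were dim, and Lpl, Tnf, Pdk4 and Lepr, which were not tested.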

Other observations

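The values here and the search for them were chosen only after the data were seen. Probes with a gap of at least 2 on the log2 scale between arrays included RT1-M5, an MHC class I gene on chromosome 20, at 4.33 in control 4 and -0.16 to -0.01 elsewhere. RT1-Bb, an MHC class II gene, was at -3.88 in cafeteria 13. The trypsin genes Prss2 and Try10, which lie on chromosome 4 within the T cell receptor beta locus, were at 2.56 and 2.44 in control 1 and at -0.14 or below elsewhere. Mfge8 was at 1.87 in control 1, Trim25 at -2.84 in control 13, Adamts13 at 1.33 in cafeteria 13, and Cbll1 at -2.98 and -2.61 in cafeteria 1 and 13.

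In 53 genes only the upstream of 2 probes was lower in cafeteria animals at an unadjusted p under 0.01. Examples are Ptms (-0.94 upstream, 0.072 downstream), Cdkn1b (-0.86 and 0.11), an inhibitor of the cell cycle, and Zfp91 (-0.51 and 0.070). With the probe of highest signal 39 genes were higher and 143 lower at that threshold, and with the probe nearest the 3' end 39 and 115, with another probe used for 827 genes.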
